A study of Rattus norvegicus with 55 samples.

How the data were processed

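RNA of the rat ventral hippocampal CA3 region was measured on 55 one-colour oligonucleotide arrays, 1 array per animal per the labels. Pups with hyperthermia-induced seizures (HS) and normothermic controls were sampled at postnatal days 12, 30, 60 and 120 (P12 to P120), which lie 1, 19, 49 and 109 days after the seizures. The labels give each animal its group and number and state no pairing or pooling. The animals' sex is not given in the sources used here.

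Per the file headers, the authors extracted each array with Agilent Feature Extraction 11.5.1.1 under a one-colour protocol, for a probe design annotated on build rn4. The submitters' processing notes list version 9.5.3.1 instead, and the files do not say why. The deposited signal columns of the array files hold intensity, the brightness of each spot, and the processed signal is background-subtracted and detrended within 1 array without scaling between arrays. Deposited columns of another kind hold flags, such as whether a spot lies well above background. The deposited series table holds log2 values for 13267 probes with 7496 empty cells, and all of its columns have the same median of 9.41. How that table was scaled and centred is not given in the sources used here. Its values followed log2 processed signal across probes of each array (Pearson r 0.9913 to 0.9999, slope 0.77 to 1.51), and differences between arrays followed those after quantile normalization with r of at least 0.864, so it served as an alternative only.

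Each array held 44254 spots, 42877 of them for genes, which make 30367 probes, and 1390 of the probes are printed on 10 spots. Spots that the deposited flags mark as outliers were dropped and repeated spots were averaged. No gene probe was saturated on any array. Names came from a RefSeq table of gene names (assembly GRCr8) through the probes' accessions for 18758 probes and through the symbol for 2050, while 9559 kept the name in the array files. No genome of the build was at hand, so coordinates are those of the probes as the array files give them (rn4), and 29522 probes have them. This left 26353 genes, each represented by its probe with the highest mean over all 55 arrays.

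The level of a gene is log2 of the processed signal minus the array's 75th percentile, so 0 is the brightness at that percentile. A gene was tested where its probe was well above background on at least 6 arrays of the fit. HS and control were compared at each age in a separate fit with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3 with statmod 1.5.0 and data.table at version 1.17.8). Genes at a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen. The 26 controls were compared between neighbouring ages in 1 fit. A moderated F test over all 55 arrays asked whether the HS effect differed between ages. Where no array of a group had a gene well above background, the fold is a bound: the group is set, array by array, to the lowest signal well above background if its own value lies below that, and the text writes "at least".

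The 29 gene lists cover 17 pathways (immediate-early genes, heat-shock chaperones, unfolded protein response, inflammatory mediators, interferon response and antigen presentation, reactive astrocyte genes, GABA signalling, glutamate receptors, voltage-gated and HCN channels, synaptic vesicle cycle, cholesterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, circadian clock, glucocorticoid-responsive genes, cell cycle, immature neuron and axon growth) and 12 cell types or tissues (microglia, astrocytes, oligodendrocytes and myelin, interneurons and neuropeptides, choroid plexus, endothelium and mural cells, meninges and fibroblasts, red blood cells, dentate gyrus granule cells, CA1 pyramidal cells, CA3 pyramidal cells, thalamus). Sex-linked genes were not used. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists and the 4 ages, or the lists and the 3 age steps, and again with an estimated correlation. Counts of single genes are given over all genes tested and adjusted over the list alone. The median of each list was also set beside 10000 random lists of genes drawn from the same 20 bins of level.

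The 3000 genes with the largest median absolute deviation at each age were clustered into 12 modules by Ward's method on 1 minus Pearson r. The principal component of each module that held most variance was compared between HS and control by a two-sided exact permutation test, adjusted over the 48 modules. The HS fold changes of 2 ages were correlated across genes, with p from 100 relabellings.

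The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule took genes with a symbol: at each age the 10 largest rises and 10 largest falls among genes that passed, or the 10 genes with the smallest p where fewer than 5 passed, up to 4 members of each list that camera called, and Fos, Arc, Bdnf, Hspa1b, Hspb1, Il1b, Gfap, Npy and Slc12a5, which were fixed by name. For the interaction it took the 10 genes with the smallest p, and for each age step the 8 largest rises, the 8 largest falls and up to 3 members of each called list, always without probes saturated on every array of a group. The share of those genes that is printed was set after their values were seen: all of them at P60, otherwise the 5 with the smallest p, 4 rises and 4 falls per age step, 2 members per list (1 from P60 to P120) and up to 3 of the genes fixed by name. A few genes that this share would include are not reported here. They stay in every count and list.

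Alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, no filter, a filter on every array, all probes, the deposited table, 1 fit of all 8 groups, slide as a random or fixed block, slides with both groups only, a replicate block, array weights, an estimated correlation, and other numbers of genes and modules. Leaving out single arrays or the P120 arrays, normexp for the lists and the random lists of like level were added after the data were seen. Results were also compared with 100 splits of the samples into groups of the same sizes, drawn with a fixed seed. The steps were tested on simulated data with 100 genes changed by 1 and 100 genes changed by 2 on the log2 scale. Of these, 33% and 89% were recovered at P12 (17539 genes), 57% and 92% at P30 (19217 genes), 75% and 97% at P60 (18391 genes) and 95% and 100% at P120 (25548 genes). The step from P12 to P30 in controls recovered 45% and 90% (25713 genes), and the interaction test 36% and 75% (25883 genes). False calls were 7 of 129 at P12, 9 of 158 at P30, 10 of 182 at P60, 9 of 204 at P120, 5 of 140 for the age step and 2 of 113 for the interaction. The simulated genes and arrays were drawn independently, without slide or scan effects or outlying arrays. These shares therefore do not give the rates on the real arrays.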

Results

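Gene expression was measured on 55 arrays of the rat ventral hippocampal CA3 region, from pups that had hyperthermia-induced seizures (HS), a model of febrile seizures, and from normothermic controls. The groups held 7 control and 7 HS animals at P12, 6 and 6 at P30, 6 and 8 at P60, and 7 and 8 at P120. Every value below is a log2 level relative to the 75th percentile of its array unless stated otherwise, errors on levels are SD, errors on log2 fold changes are SE, and the number of arrays limits the precision.

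The arrays of P120 stood apart in brightness. Their negative-control spots read 181 to 721 intensity units in controls and 187 to 782 in HS animals, against 37.4 to 58.9 in the 40 arrays of the other ages, and 93.5% to 98.2% of their probes lay well above background, against 54.1% to 83.4%. The median of 1425 probes for olfactory, vomeronasal and trace-amine receptors, which hippocampal tissue hardly expresses, was -2.18 to -1.78 at P120 and -8.47 to -5.54 at the other ages. P120 arrays shared no slide or scan with another age. HS and control animals lay on separate slides at P120, and shared only some slides at the other ages.

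**Figure D1:**
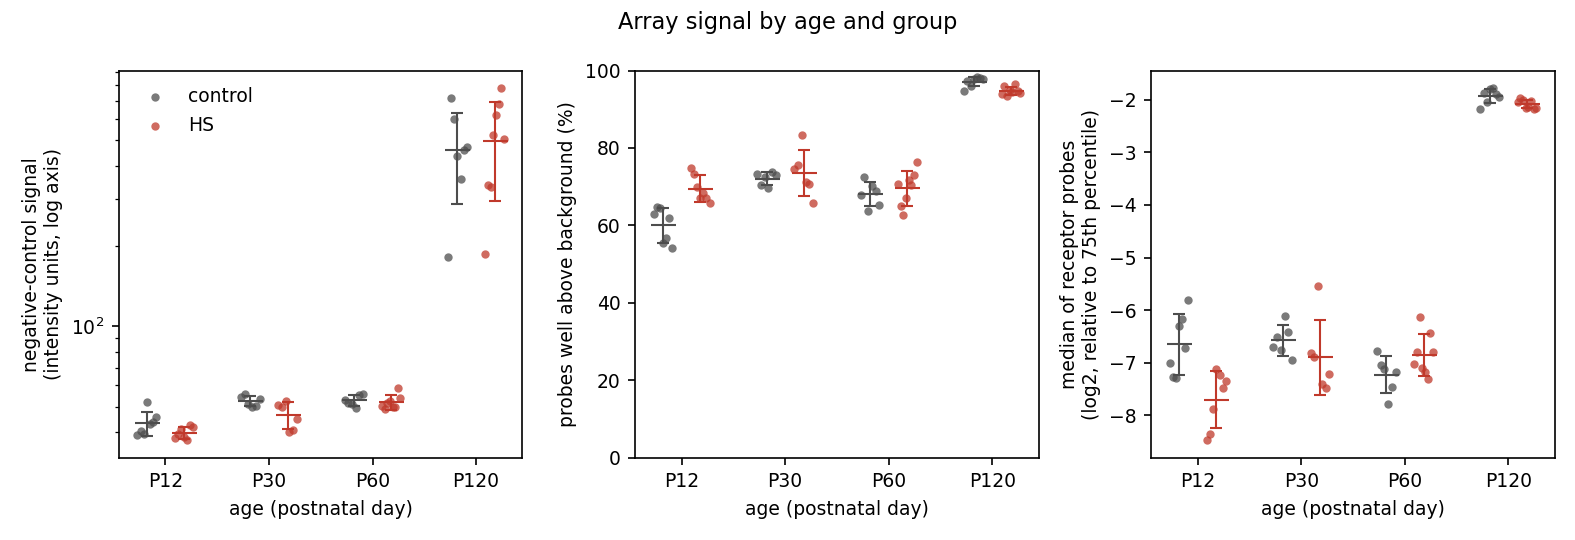
Negative-control signal (intensity units, log axis), percent of probes well above background, and the median of 1425 receptor probes (log2, relative to the 75th percentile) on each array, by age, with control arrays in grey and HS arrays in red. Points are arrays and bars are mean and SD. The 15 arrays of P120 lie apart on all 3 measures.

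The P12 comparison asks what the acute stage, 1 day after the seizures, looks like. Snx30, a sorting nexin of endosomal membrane traffic (probe on chromosome 5, 78031118 to 78035492), rose from -5.46 ± 0.29 (n = 7) in controls to -4.14 ± 0.34 (n = 7) in HS animals, at least 1.39-fold, with no control array well above background. Its log2 fold change was 1.32 ± 0.19 (adjusted p = 0.0347), and 7 of 7 HS arrays lay above the control mean. Of all probes, 54.1% to 64.7% lay well above background on P12 control arrays and 65.8% to 74.8% on P12 HS arrays. Detection in HS animals alone therefore does not mark single genes at this age. The other of the 2 genes that passed, out of 17558 tested, has no symbol. Slc28a1, a nucleoside transporter, had a log2 fold change of 1.79 ± 0.29 (adjusted p = 0.0758) and Trib3, a pseudokinase induced by cell stress, one of 1.33 ± 0.25 (adjusted p = 0.245), both higher on 7 of 7 HS arrays without passing. As no control array had Slc28a1, Trib3 or Fut7 well above background, their folds are not exact, and the bound is 1.01-fold for Trib3 and gives no fold for Slc28a1 or Fut7. Fut7, a fucosyltransferase, and Or2av10, an olfactory receptor, had values of 1.05 ± 0.20 and 1.19 ± 0.24 (adjusted p = 0.269 for both).

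Among the gene groups at P12, 6 lists were called downward, and none with an estimated correlation. The cell cycle list was shifted down (camera adjusted p = 0.00111, adjusted p = 0.898 with an estimated correlation), with 17 of 24 members lower and a median of -0.19. Cdk1 and Ccnb1, which drive mitotic entry, had log2 fold changes of -0.76 ± 0.23 and -0.74 ± 0.23 (adjusted p = 0.536 and 0.546), and 4 members passed as falls when adjusted over the list alone. Markers of endothelium and mural cells were also shifted down (adjusted p = 0.0367, 0.898 with an estimated correlation, 16 of 19 lower, median -0.22), with Egfl7 at -0.53 ± 0.19 and the pericyte gene Rgs5 at -0.52 ± 0.27 (-0.26 without P12 control 7). The lists of immature neurons and axon growth (adjusted p = 0.00408, 15 of 19 lower, median -0.22, Marcksl1 -0.53 ± 0.17, Igfbpl1 -0.57 ± 0.21) and red blood cells (adjusted p = 0.0367, 7 of 8 lower, median -0.39, Ahsp -0.92 ± 0.35, Hba-a1 -0.48 ± 0.26) were shifted down under the main scaling. Neither was called by camera with quantile normalization (adjusted p = 0.197 and 0.161) or normexp (0.247 and 0.143).

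Genes of protein synthesis and respiration gave the smallest list p at P12, and these depended on 1 array and on how arrays were scaled. Cytosolic ribosomal proteins were shifted down (adjusted p = 4.79e-12, 65 of 69 lower, median -0.46, Rpl28 -0.76 ± 0.31), as was oxidative phosphorylation (adjusted p = 0.000153, 45 of 56 lower, median -0.33), where Cox4i1 of complex IV had -0.44 ± 0.19. P12 control 7 had a ribosomal median of 7.96, against 5.66 to 6.08 on the other controls, and without it the ribosomal median shift was -0.19 (57 of 69 lower, adjusted p = 0.000116), that of oxidative phosphorylation -0.12 (adjusted p = 0.0709) and Rpl28 -0.47 ± 0.17. After quantile normalization the ribosomal median was -0.07 (adjusted p = 0.252) and the oxidative phosphorylation median 0.00 with the test turned upward (adjusted p = 0.894), and Cox4i1 turned to 0.04. Random genes of the same level as the ribosomal list had a median of -0.30 at P12, so genes as bright as these read lower in HS animals there. No member of these 6 lists passed over all genes, and all 6 had an adjusted p = 0.898 with an estimated correlation. Cell cycle kept its call under quantile and normexp scaling, a fixed slide block, a replicate block and without P12 control 7, while endothelium lost it under the fixed slide block, where the test turned upward (adjusted p = 0.487).

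Receptor probes, read as a measure of dim signal, were lower in HS animals at P12: -7.70 ± 0.55 (n = 7) against -6.65 ± 0.57 (n = 7; exact permutation p = 0.00408). Snx30 passed in 4 of 10 alternatives, with adjusted p from 0.00431 to 0.790, and not with slide as a random block (0.11). The count of 2 ranged from 0 to 18 when 1 array at a time was left out: it was 18 without P12 control 5, 1 without P12 control 2 or P12 HS 5, 2 without P12 control 7, and 0 without any of the others. It was 71 with array weights (65 upward), 1203 with all 8 groups in one fit (613 upward) and 2754 with no filter on dim probes (124 upward, 2630 downward). Without P12 control 7 the red blood cell call was lost too (adjusted p = 0.255, median -0.21), and other splits of the 14 arrays called up to 134 genes and 11 lists.

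At P30, 19 days after HS and in the latent stage, no single gene passed among 19237 tested with limma (smallest adjusted p = 0.794). The count at an unadjusted p under 0.05 was 1167, where 962 are expected by chance, and the alternatives gave 0 to 5 genes. The 5 genes with the smallest p were all lower on 6 of 6 HS arrays. Itpripl1 had a log2 fold change of -1.30 ± 0.23, Slc6a12, a betaine and GABA transporter, -0.81 ± 0.16, and Odam, an enamel protein, -1.78 ± 0.38. Dse, a dermatan sulfate epimerase, had -0.55 ± 0.12 and Or52z1, an olfactory receptor, -1.49 ± 0.32 (adjusted p = 0.794 for all).

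Markers of meninges and fibroblasts were shifted up at P30 (adjusted p = 1.73e-05, 14 of 14 members higher in HS animals, median 0.53). Slc22a6, an organic anion transporter, had 1.06 ± 0.33 and Slc6a13, a GABA transporter of the meninges, 0.76 ± 0.26. Reactive astrocyte genes were shifted up (adjusted p = 0.0457, 13 of 17 higher, median 0.20), with Gfap, the intermediate filament of astrocytes, at 0.73 ± 0.31 and higher on 6 of 6 HS arrays, and Tgm1 at 1.15 ± 0.54. Cytosolic ribosomal proteins were shifted down (adjusted p = 0.000189, 68 of 69 lower, median -0.18, Rpl22 -0.42 ± 0.23, Rplp2 -0.30 ± 0.19), as was the cell cycle list (adjusted p = 0.00663, 19 of 21 lower, median -0.31, Cdc20 -0.51 ± 0.15, Aurkb -1.23 ± 0.52). P30 control 4 had a ribosomal median of 6.52, against 5.32 to 5.72 on the other P30 controls and 5.22 to 5.63 on the P30 HS arrays. The synaptic vesicle cycle (adjusted p = 0.0451, 17 of 21 higher, median 0.19, Stx1a 0.60 ± 0.26 and 0.36 ± 0.16 without P30 control 3, Cplx2 -0.49 ± 0.21) and CA1 pyramidal cell lists (adjusted p = 0.0451, 6 of 7 higher, median 0.56, Wfs1 1.07 ± 0.35) were shifted up. Cplx2 turned to 0.18 with slide as a fixed block. No member passed, over all genes or adjusted over the list alone, and all 6 lists had an adjusted p = 0.898 with an estimated correlation.

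P30 control 3 carried part of this. On that array a list of striatal projection neuron genes had a median of 1.91, against -2.74 to -1.89 on the other 11 P30 arrays, and a list of hippocampal glutamatergic genes -3.18, against 0.90 to 1.64. Without it 0 of 19045 genes passed (1056 at an unadjusted p under 0.05). The cell cycle (adjusted p = 0.613), synaptic vesicle (0.533) and CA1 (0.134, median 0.07) calls were then lost. Those of meninges (0.000346, median 0.40), ribosomal proteins (0.000599, median -0.18) and reactive astrocytes (0.00594, median 0.28) remained, and microglia (0.00092, 14 of 18 higher, median 0.19), endothelium (0.0324, median 0.18) and immediate-early genes (0.034, median 0.21) were called as well. The ribosomal call was not tested without P30 control 4, which was high in that list. The other P30 controls had list medians of 5.32, 5.44, 5.72, 5.35 and 5.41, and the P30 HS arrays 5.43, 5.25, 5.22, 5.63, 5.59 and 5.58. These values overlap, so how far the ribosomal call rests on P30 control 4 stays open. The reactive astrocyte call held in 2 of 6 alternatives with a preset correlation: it was lost with quantile normalization (0.0627), normexp (0.134), slide as a fixed block (0.819) and without P30 control 1 and P30 HS 6 (0.153). With an estimated correlation and without that array, microglia had an adjusted p = 0.857 and reactive astrocytes 0.672 with an estimated correlation, and the other 4 lists 0.898. With slide as a fixed block the meningeal test turned downward (adjusted p = 0.633) and of the 6 calls only the ribosomal one was kept (0.0472), and other splits of the 12 arrays called up to 13 lists.

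**Figure D2:**
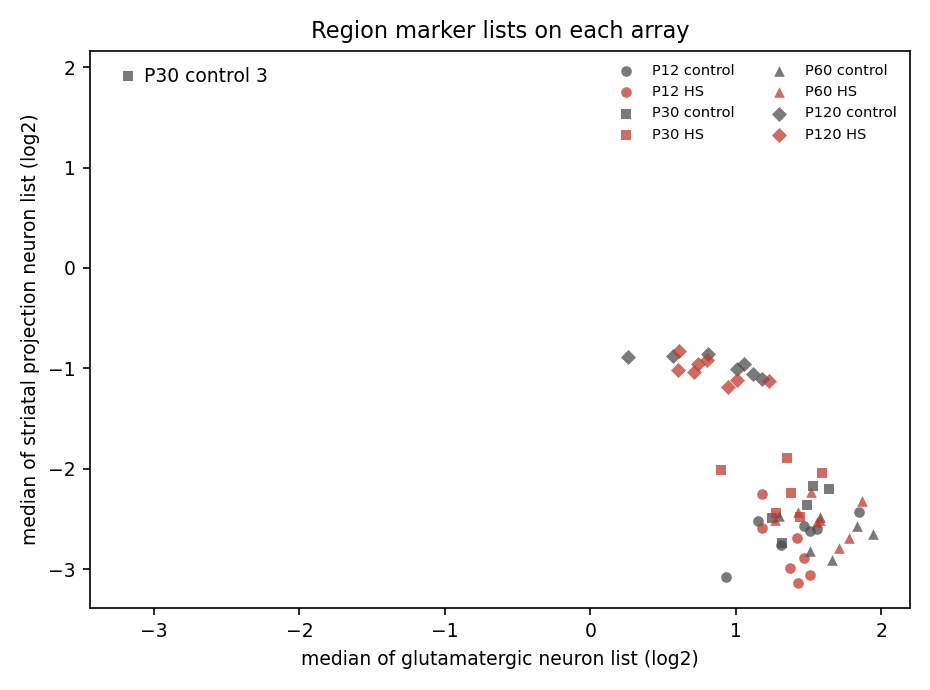
Median of 13 hippocampal glutamatergic neuron genes (x, log2) against the median of 26 striatal projection neuron genes (y, log2) on each of the 55 arrays, by age and group. P30 control 3 lies at -3.18 and 1.91, and the other 54 arrays lie at 0.26 to 1.94 and -3.13 to -0.83.

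At P60, 49 days after HS, 116 of 18411 genes passed, and 113 of them were higher in HS animals. Glp1r, the receptor of the incretin GLP-1, rose from -6.24 ± 0.31 (n = 6) to -4.69 ± 0.70 (n = 8), at least 1.86-fold, with no control array well above background and a log2 fold change of 1.55 ± 0.28 (adjusted p = 0.0331; chromosome 20, 9258276 to 9259805). Aqp2, the vasopressin-regulated water channel, rose by 1.05 ± 0.18 (adjusted p = 0.0287) and Ido2, an enzyme of tryptophan breakdown, by 1.18 ± 0.21 (adjusted p = 0.0313). Otop1, a proton channel, rose by 1.15 ± 0.22 (adjusted p = 0.0387), and Tasl, an adaptor in Toll-like receptor signalling, by 0.99 ± 0.19 (adjusted p = 0.0359). The olfactory receptor genes Or51i2 (1.44 ± 0.30), Or4c127 (1.09 ± 0.18) and Or6ae1 (1.00 ± 0.21), the tripartite-motif gene Trim42 (1.29 ± 0.27) and Prrg4 (0.98 ± 0.21) complete the 10 largest rises (adjusted p from 0.0287 to 0.0477). Among the 3 genes that fell were Cep19, a centrosomal protein (-0.53 ± 0.11, adjusted p = 0.047), and Samd8, an enzyme of sphingolipid synthesis (-0.45 ± 0.09, adjusted p = 0.047). Each of these 12 genes moved in its direction on 8 of 8 HS arrays.

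**Figure D3:**
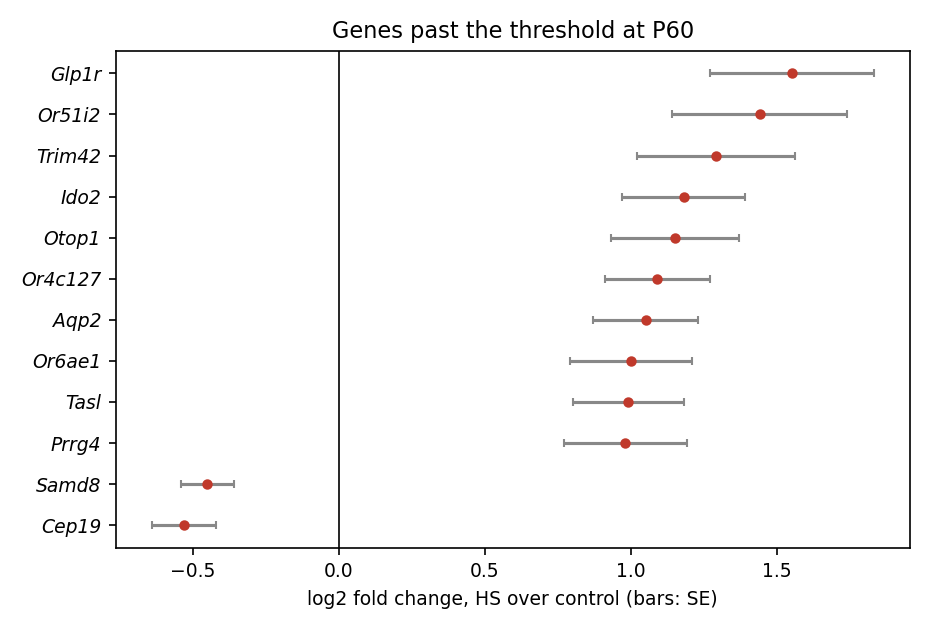
Log2 fold change, HS over control, of the 10 largest rises and 2 of the 3 falls among the genes that passed at P60. Points are limma estimates and bars are SE, from 8 HS and 6 control arrays. The rises run from 0.98 to 1.55 and the falls from -0.53 to -0.45. The largest, that of Glp1r, is not exact, as no control array had it well above background.

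Cholesterol biosynthesis was shifted down at P60 (adjusted p = 5.12e-05, 22 of 24 members lower, median -0.15). Stard4, which carries cholesterol between membranes, had -0.41 ± 0.13 (adjusted p = 0.119) and Lss, lanosterol synthase, -0.39 ± 0.14 (adjusted p = 0.165), and no member passed. This call held in 4 of 4 alternatives with a preset correlation (adjusted p 0.000671 to 0.00547). Interferon response and antigen presentation was shifted down (adjusted p = 0.0119, 12 of 19 lower, median -0.15), with the transcription factor Irf7 at -0.51 ± 0.14 (adjusted p = 0.0912) and the immunoproteasome subunit Psmb8 at -0.56 ± 0.16 (adjusted p = 0.0923). Adjusted over the list alone, 2 of its members fell. Oxidative phosphorylation was shifted down as a set (adjusted p = 0.0367, 37 of 56 lower, median -0.04, Atp5f1c -0.20 ± 0.07), while Uqcrq of complex III rose by 0.69 ± 0.14 (adjusted p = 0.047). All 3 lists had an adjusted p = 0.898 with an estimated correlation. With slide as a fixed block the tests of the interferon (0.865) and oxidative phosphorylation (0.239) lists turned upward. Markers of myelin (19 of 20 higher, median 0.27) and of meninges (11 of 14 lower, median -0.31) missed the threshold (adjusted p = 0.0627 for both).

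The 113 genes that rose at P60 had a median level of -3.28, against -1.03 for all genes tested, and 83 of them were well above background on all 14 arrays. With only such genes tested, 145 passed, 138 of them upward, and they held 86 of the 116. Of the 3000 most variable genes, 1 module of 526 differed between HS and control (exact permutation p = 0.000333, adjusted p = 0.016), with a median level of -4.58. It held 61 of the 73 risen genes that were clustered, where random placement gives 12.8, and 31 of the 84 receptor probes clustered, so that such probes made up 5.9% of the module and 2.8% of all genes clustered. As the risen genes were chosen for a difference on the same arrays, they tend to cluster together. Their overlap with the module is therefore no separate support. The median of the receptor probes was -6.85 ± 0.40 (n = 8) in HS animals and -7.23 ± 0.35 (n = 6) in controls (exact permutation p = 0.0906). The count of 116 fell to 0 with quantile normalization or slide as a random block, and was 210 with slide as a fixed block, 110 upward and 100 downward, of which 8 were among the 116. The median log2 fold change of the risen genes was 0.79, and in these settings 0.56 (SE 0.116), 0.81 (SE 0.174) and 0.69 (SE 0.248). The count of genes ranged from 0 to 199 when 1 array was left out: it was 199, 188 and 190 without P60 control 2, P60 HS 4 and P60 HS 5, 27 to 64 without P60 control 5, control 6, HS 1, HS 2 or HS 7, 2 without P60 control 4, and 0 without P60 control 3, HS 3, HS 6 or HS 8.

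At P120, 109 days after HS and in the chronic stage, no gene passed among 25568 tested with limma, while 5 genes with the smallest p shared an adjusted p = 0.0605. All were lower on 8 of 8 HS arrays, which lay on other slides than the controls. The receptor probes were lower in HS animals as well, at -2.08 ± 0.08 (n = 8) against -1.93 ± 0.14 (n = 7; exact permutation p = 0.0294). Chrna2, a nicotinic receptor subunit of a class of hippocampal interneurons, had a log2 fold change of -0.63 ± 0.11, the keratin Krt14 -0.99 ± 0.16, and the lipoxygenase Alox12e -0.80 ± 0.13. Myo18a, an unconventional myosin, had -0.42 ± 0.07 and Rrh, a retinal opsin, -0.39 ± 0.07. The count at an unadjusted p under 0.05 was 2619, where 1278 are expected by chance. The alternatives gave 0 to 402 genes, and leaving out 1 array gave 530 without P120 control 1, 334 without P120 control 3, 16 without P120 HS 6 and 0 otherwise.

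The list shifts at P120 were all upward and small, on arrays whose levels were less spread than at the other ages. Cytosolic ribosomal proteins had 44 of 69 members higher (adjusted p = 0.00231, median 0.04, Rpl37l1 0.22 ± 0.11, Rpl36 0.20 ± 0.10) and oxidative phosphorylation 33 of 56 (adjusted p = 0.0389, median 0.02, Atp5g3 0.12 ± 0.06, Atp5f1d 0.16 ± 0.09). Microglial genes had 14 of 18 higher (adjusted p = 0.0367, median 0.05), with the protease Ctss at 0.24 ± 0.09 and the receptor Trem2 at 0.15 ± 0.07. Genes of immature neurons and axon growth had 13 of 20 higher (adjusted p = 0.0367, median 0.05), with Gap43 at 0.25 ± 0.09 and Cd24 at 0.22 ± 0.08. In the synaptic vesicle cycle 13 of 21 were higher (adjusted p = 0.0457, median 0.06), with Sv2a, a vesicle glycoprotein, at 0.35 ± 0.10 and Cplx2 at 0.46 ± 0.18, and 1 member rose when adjusted over the list alone. All 5 lists had an adjusted p = 0.898 with an estimated correlation, none was called after quantile normalization (adjusted p 0.161 to 0.857), and other splits of the 15 arrays called up to 14 lists.

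Of the genes fixed by name and listed in the methods, 8 could be tested at P12, P30 and P60 and 9 at P120, and none passed with limma (1, 1, 0 and 2 at an unadjusted p under 0.05). Gfap had log2 fold changes of 0.80 ± 0.40 at P12 (6 of 7 HS arrays higher, adjusted p = 0.566), 0.73 ± 0.31 at P30 (adjusted p = 0.794), -0.33 ± 0.30 at P60 (adjusted p = 0.602) and -0.14 ± 0.10 at P120 (adjusted p = 0.763). Npy, a peptide of interneurons, had -0.77 ± 0.28 at P12 (7 of 7 lower, adjusted p = 0.551), and Bdnf, a neurotrophin, 0.34 ± 0.26 (adjusted p = 0.647). The chaperone Hspa1b had 0.58 ± 0.40 at P30 (adjusted p = 0.795), and 0.27 ± 0.31 without P30 control 3. Fos, an immediate-early gene, had 0.49 ± 0.35 at P60 (adjusted p = 0.49). Slc12a5, the neuronal chloride exporter, had -0.13 ± 0.10 at P60 (adjusted p = 0.514) and -0.27 ± 0.12 at P120 (adjusted p = 0.444), where Hspa1b had -0.48 ± 0.18 (adjusted p = 0.297). Across these genes the values ran from -0.77 to 0.80 at P12, 0.01 to 0.85 at P30, -0.33 to 0.49 at P60 and -0.48 to 0.11 at P120. The 0.85 is Bdnf, which was at -7.44 on P30 control 3, and without that array its value was -0.09 ± 0.20. With slide as a fixed block, Gfap at P60 turned to 0.39.

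The HS effect differed between ages for 2460 of 25883 genes in the F test, but 1502 of these were well above background on fewer than 6 of the 40 arrays of the other ages, and the median of the 2460 was 2 of 40. Among the 10 with the smallest p were Marveld3, a tight-junction protein (P12 -1.46, P30 -1.18, P60 0.98, P120 -0.03, adjusted p = 0.00603), Serpina6, the corticosteroid-binding globulin (-1.46, -1.45, 1.24 and -0.01, adjusted p = 0.0068), and Pkhd1, a ciliary protein (-1.12, 0.09, 1.34 and -0.07, adjusted p = 0.0068). C2h4orf46 had the smallest p (-0.75, -0.97, 1.22 and -0.05, adjusted p = 0.00264), and Ifna2, an interferon, had -1.25, 0.93, 0.40 and -0.02 (adjusted p = 0.0068). Also among the 10 were Vom2r24 and Vom1r47, vomeronasal receptors, Olr716 and Or11a4, olfactory receptors, and Cfap20dc. None of these 10 was well above background on more than 7 arrays at any age but P120. Without the P120 arrays, 1 of 20496 genes passed. Between pairs of ages the effect differed for 4563 genes between P60 and P12, 432 between P30 and P12, 148 between P60 and P30, 13 between P120 and P12, and 0 between P120 and P30 (1089 at an unadjusted p under 0.05) or P60 (1533). Receptor probes, read as dim signal, also differed, with HS minus control at -1.05 at P12 and 0.38 at P60.

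Across genes, which are not independent replicates, no pair of ages had HS fold changes whose correlation passed the permutation test. Pearson's r was -0.278 between P30 and P60 (permutation p = 0.06, adjusted over 6 pairs 0.36), -0.215 between P12 and P30 (0.37, adjusted 0.86) and between -0.081 and 0.05 for the other 4 pairs (p from 0.46 to 0.86, adjusted 0.86). Of 12 co-expression modules at each age, 1 passed the exact permutation test at P60 and 0 at P12, P30 and P120 (smallest adjusted p 0.112, 0.273 and 0.112, with 2, 1 and 1 at an unadjusted p under 0.05). After quantile normalization 1 passed at P12 (adjusted p = 0.0466) and 1 at P120 (0.0298).

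From P12 to P30 in controls, myelin genes rose and genes of growing neurons and dividing cells fell. No P12 control shared a slide or scan with a P30 control, so age and batch could not be told apart in this step. Mal, a myelin membrane protein, went from -6.05 ± 0.64 (n = 7) to 1.95 ± 0.93 (n = 6), at least 99.9-fold (adjusted p = 9.45e-15; chromosome 3, 115167515 to 115167574). Hapln2, a link protein of the nodal matrix, rose by 6.75 ± 0.30 (adjusted p = 9.61e-15), Klk6, a protease of oligodendrocytes, at least 28.3-fold (adjusted p = 1.67e-12), and the oligodendrocyte gene Opalin by 6.17 ± 0.45 (adjusted p = 3.31e-10). Madcam1, a vascular addressin, fell at least 8.97-fold (adjusted p = 1.72e-11). Col26a1, a collagen, Fbp2, a gluconeogenic enzyme, and Slc38a5, a glutamine transporter, fell with log2 fold changes of -3.80 ± 0.29 (adjusted p = 4.8e-10), -3.24 ± 0.26 (1.34e-09) and -3.16 ± 0.24 (3.57e-10). Each moved in its direction on 6 of 6 arrays of P30.

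Of the myelin list, 16 of 20 members rose and none fell (camera adjusted p = 9.78e-13, 0.193 with an estimated correlation, median 2.73), among them Mobp (5.86 ± 0.35). Of the immature neuron and axon growth list, 16 of 20 fell (17 adjusted over the list alone; adjusted p = 2.12e-15, median -1.70), including Dpysl3 (-2.87 ± 0.27) and Dpysl5 (-2.66 ± 0.23), which steer axon outgrowth. This list alone was called with an estimated correlation (adjusted p = 0.000111). Of the cell cycle list 18 of 25 fell (adjusted p = 7.36e-11, 0.193 with an estimated correlation, median -1.15), with Cdk1 at -2.41 ± 0.35 and Ccna2 at -1.95 ± 0.37. Of the astrocyte list 5 of 15 rose (adjusted p = 0.0174, 0.205 with an estimated correlation), with the connexin Gjb6 going from 0.29 to 2.29 and the potassium channel Kcnj10 at 1.58 ± 0.24 from levels not well above background on any P12 control, so without a fold. Of the voltage-gated channels 13 of 32 rose and 1 fell (adjusted p = 0.0203, 0.512 with an estimated correlation), including Scn2b (1.47 ± 0.27) and Scn4b (3.97 ± 0.68, 5.59 on P30 control 3 and -1.33 to 0.20 on the other P30 controls). Of the circadian clock list 8 of 16 rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.0231, 0.308 with an estimated correlation), with Nr1d2 at 2.11 ± 0.24 and Bhlhe40 at 1.75 ± 0.48. Of cholesterol biosynthesis 13 of 24 fell (adjusted p = 0.000216, 0.329 with an estimated correlation), with Tm7sf2 at -1.64 ± 0.22 and Mvd at -1.29 ± 0.19.

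Oxidative phosphorylation (22 of 56 fell, 1 rose, 25 falls adjusted over the list alone; adjusted p = 1.1e-06, 0.512 with an estimated correlation) and ribosomal proteins (15 of 69 fell, 1 adjusted over the list alone; adjusted p = 6.69e-07, 0.644 with an estimated correlation) were shifted down by medians of -0.46 and -0.49, which quantile normalization reduced to -0.07 and -0.02 (adjusted p = 0.758 and 0.934) and leaving out P12 control 7 to -0.26 and -0.17 (adjusted p = 4.75e-05 and 0.00104). Cox5a and Uqcrc1 fell by 1.03 ± 0.21 and 0.99 ± 0.20, and Rps2 and Rps18 by 0.94 ± 0.20 and 0.86 ± 0.26 with 5 of 6 arrays in that direction. In all, 9415 of 25713 genes changed, 61.3% of them upward (46.5% after quantile normalization), and 8299 without P30 control 3. Without that array 20 of 25 cell cycle genes fell (adjusted p = 0.00123 with an estimated correlation) and dentate granule cell genes were called upward (7 of 9, adjusted p = 0.00387, 0.244 with an estimated correlation), and the channel and clock calls were lost without P12 control 7, and also without the P120 arrays (adjusted p = 0.0544 and 0.0653).

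**Figure D4:**
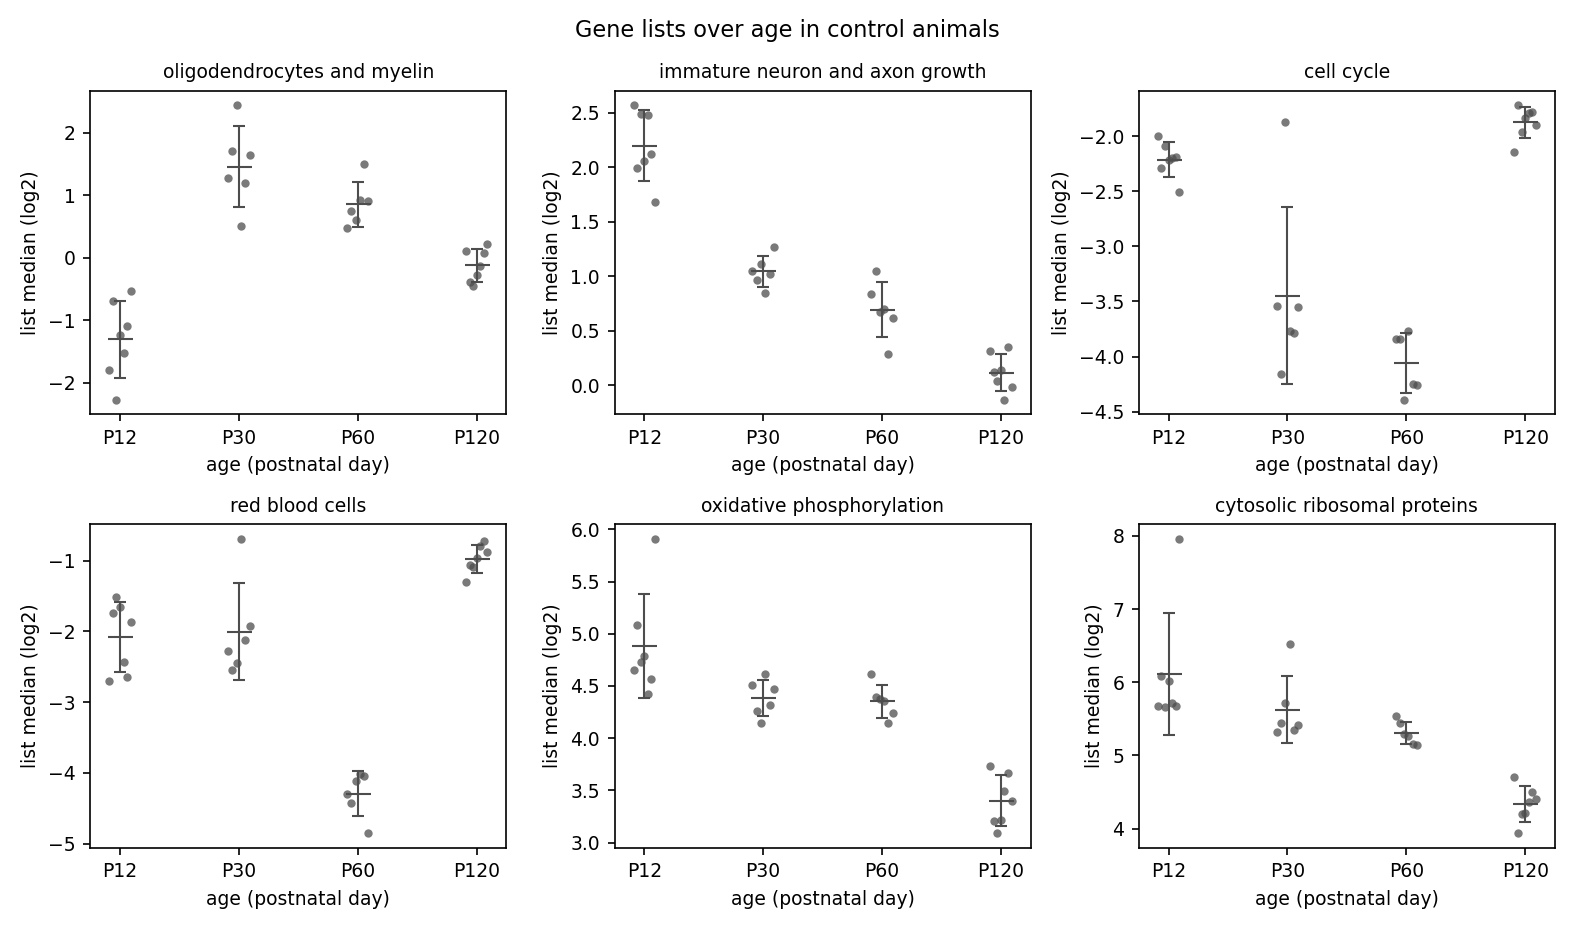
Median level (log2, relative to the 75th percentile) of 6 gene lists on each of the 26 control arrays, by age. Points are arrays and bars are mean and SD. Myelin genes rise from P12 to P30 while immature neuron and cell cycle genes fall, and red blood cell genes are lower at P60 than at P30.

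From P30 to P60 in controls, red blood cell genes fell and the list of interferon response and antigen presentation was shifted up. Of the red cell list 9 of 11 members fell (adjusted p = 2.79e-07, 0.111 with an estimated correlation, median -2.14). The anion exchanger Slc4a1 fell at least 4.61-fold (adjusted p = 2.6e-09) and the globin Hbe2 by 2.45 ± 0.43 (adjusted p = 0.000252), both on 6 of 6 arrays. Of the interferon response and antigen presentation list 5 of 20 rose (adjusted p = 8.61e-07, 0.0376 with an estimated correlation, median 0.31). Irf7 rose by 1.65 ± 0.25 (adjusted p = 3.91e-05) and Ifi27, an interferon-induced gene, by 1.53 ± 0.23 (adjusted p = 4.6e-05). Of the heat-shock chaperones 4 of 19 rose (adjusted p = 3.28e-06, 0.0986 with an estimated correlation, median 0.32), with the cochaperone Stip1 at 0.82 ± 0.18 and Hspa1b at 1.20 ± 0.39. Of CA3 pyramidal cell genes 3 of 9 rose (4 adjusted over the list alone; adjusted p = 0.0031, 0.111 with an estimated correlation), with Prss23 at 1.27 ± 0.32 and the kainate receptor gene Grik4 at 1.16 ± 0.39, and 1 of 9 without P30 control 3.

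Among single genes, Hes1, a Notch target, rose at least 5.61-fold (adjusted p = 2.38e-05), Gnrhr by 2.71 ± 0.56, Or9m1b by 2.31 ± 0.59 and Tmem215 by 2.27 ± 0.55. Cldnd2 fell at least 5.47-fold (adjusted p = 2.1e-06), the olfactory receptor gene Or12d2b at least 9.23-fold and the hair keratin Krt33b at least 4.62-fold, with no P60 control array well above background for any of them. P30 control 1, the only P30 control scanned with P60, stood apart in the direction of the change for some of these genes. It lay at -6.30 in Cldnd2 (other P30 controls -2.73 to -2.07), -5.27 in Or12d2b (-1.87 to -1.70) and -3.01 in Or9m1b (-6.04 to -5.24). For Cldnd2, Or12d2b and Or9m1b age and scan were therefore not told apart. The other 5 P30 controls were scanned apart from the P60 controls, so scan can enter the other changes of this step too. Of the synaptic vesicle list 2 of 21 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 6.31e-05, 0.348 with an estimated correlation), including a fall of Sv2c (-0.93 ± 0.32). Of the channels 4 rose and 2 fell, such as the pacemaker channel Hcn4 (-2.05 ± 0.22, at least 3.29-fold; list adjusted p = 0.00814, 0.478 with an estimated correlation). The unfolded protein response (adjusted p = 0.048, 0.464 with an estimated correlation), cholesterol biosynthesis (0.024, 0.567 with an estimated correlation) and oxidative phosphorylation (0.0304, 0.788 with an estimated correlation) were called upward with members on both sides. Asns (0.80 ± 0.21), Hsd17b7 (0.69 ± 0.23) and Atp5f1b (0.74 ± 0.21) rose while Chac1 (-1.15 ± 0.23) and Uqcrq (-1.54 ± 0.27) fell. The mean of oxidative phosphorylation was -0.02 although its test pointed up. Without the P120 arrays in the fit the calls of the channels (adjusted p = 0.1), the unfolded protein response (0.171), cholesterol biosynthesis (0.153) and oxidative phosphorylation (0.232) were lost.

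In all, 5156 of 25713 genes changed from P30 to P60 and 18.5% of them rose (40.6% after quantile normalization), with a median of -0.20 over all genes, relative to which the list shifts above were tested. Without P30 control 3 there were 4300, and no synaptic vesicle gene was then among them. For genes that fell in a fit without the array in question, P30 control 1, the only P30 array scanned with P60, lay 0.34 of the way from P60 to P30, against 0.96 to 1.26 for the other controls without control 3, and P30 HS 6, scanned apart from all of these, 0.32. Age and scan were thus not told apart for the fallen genes as a set. For red blood cell genes P30 control 1 lay at 0.88 and the others at 0.82 to 1.39.

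From P60 to P120 in controls 21564 of 25713 genes changed and the median over all genes was +1.42. The shift was larger for dim probes: receptor probes went from -7.23 ± 0.35 (n = 6) at P60 to -1.93 ± 0.14 (n = 7) at P120. Values have to be read relative to the shift at their own level. For genes not well above background at P60, the folds below bound the signal, which nonspecific signal at P120 could raise. Pkd2l1, a channel of fluid-contacting neurons, was at least 61.0-fold higher at P120, Dbx1, a homeobox gene of the embryonic nervous system, at least 60.9-fold, P2rx5, an ATP-gated channel, at least 65.2-fold and Pck1, a gluconeogenic enzyme, at least 41.9-fold. Cdc14a fell at least 2.33-fold, Edem1 at least 2.10-fold, Efnb1 at least 1.76-fold and Lsm14b at least 2.80-fold. All lay in their direction on 7 of 7 arrays. The share of changed genes that rose was 70.6%, and 47.7% after quantile normalization.

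Of the 29 lists, 15 were shifted down from P60 to P120, none of them with an estimated correlation and none after quantile normalization. Of oxidative phosphorylation 53 of 56 members fell and none rose (adjusted p = 1.96e-15, 0.264 with an estimated correlation, median -1.04, Cycs -1.51 ± 0.24), and of ribosomal proteins 63 of 69 (adjusted p = 2.12e-15, 0.48 with an estimated correlation, median -1.06, Rpl24 -1.46 ± 0.31), but after quantile normalization their medians were -0.04 and 0.02. Of cholesterol biosynthesis 20 of 24 fell and 2 rose (adjusted p = 5.59e-07, 0.193 with an estimated correlation, median -0.88), and the median stayed at -0.51 after quantile normalization. Of myelin genes 12 of 20 fell and 1 rose (adjusted p = 0.000147, 0.512 with an estimated correlation, median -1.01, and -0.78 after quantile normalization). Of the synaptic vesicle cycle 14 of 21 fell and 2 rose (adjusted p = 1.64e-05, 0.308 with an estimated correlation, median -1.10, and -0.37 after quantile normalization), with Cplx2 at -1.57 ± 0.26. Of the heat-shock chaperones 13 of 19 fell and 1 rose (adjusted p = 1.33e-05, 0.0986 with an estimated correlation, median -0.94, and -0.12 after quantile normalization), with Hspd1 at -1.42 ± 0.17.

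The other lists shifted down held members that went both ways. Astrocyte genes had 11 of 15 fall and 3 rise (adjusted p = 0.00114, 0.0986 with an estimated correlation), with Kcnj10 going from -5.04 to -0.43. GABA signalling had 11 of 23 fall and 4 rise (adjusted p = 0.00197, 0.193 with an estimated correlation), with the receptor subunit gene Gabrg3 at least 9.30-fold higher and its log2 fold change at -0.67 after quantile normalization. The unfolded protein response had 12 of 18 fall and 4 rise (adjusted p = 0.00568, 0.268 with an estimated correlation), with Trib3 going from -4.75 to -1.36 and its log2 fold change at -0.03 after quantile normalization. The channels had 14 of 32 fall and 8 rise (adjusted p = 0.0109, 0.48 with an estimated correlation, Hcn4 at least 20.8-fold higher), and interneurons and neuropeptides 9 of 18 fall and 2 rise (adjusted p = 0.0159, 0.308 with an estimated correlation, Nos1 3.64 ± 0.29). Microglia had 6 of 18 fall and 5 rise (adjusted p = 0.0174, 0.48 with an estimated correlation), with the integrin gene Itgam at 2.67 ± 0.31 and -0.10 after quantile normalization. Glucocorticoid-responsive genes had 9 of 17 fall and 5 rise (adjusted p = 0.0212, 0.268 with an estimated correlation, Hif3a 4.37 ± 0.39), and immature neuron genes 10 of 20 and 6 (adjusted p = 0.0273, 0.287 with an estimated correlation, St8sia2 at least 23.3-fold higher). Immediate-early genes had 7 of 25 fall and 8 rise (adjusted p = 0.0394, 0.467 with an estimated correlation, Egr3 5.86 ± 0.35). After quantile normalization cell cycle genes (adjusted p = 0.0312, median -1.87, against 2.09 under the main scaling) and thalamic genes (adjusted p = 0.0415, median -1.98) were called downward instead. As P120 was hybridized and scanned apart from the other ages, age and batch could not be told apart for any of these genes.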

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

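The lists of tissue genes, the tests of background, slide, nonspecific signal and scan, the reading of the scaled folds at P60, Dixon's test on these values and the other splits of the samples were chosen only after the results they examine had been seen, while the scalings and the F test were planned.

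P30 control 3 carried striatal transcripts and was low in most of the hippocampal ones listed. Drd2, a dopamine receptor of striatal projection neurons, was at 4.67 on that array, against -2.08 ± 0.48 on the other P30 arrays. Rgs9 (5.30 against -1.34), Adora2a (3.18 against -3.60), Penk (4.58 against -1.19) and Ppp1r1b (5.75 against 0.51), all striatal genes, stood out alike. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, was at -5.99 against -0.67, and the transcription factor genes Neurod1 (-7.64 against 0.50) and Neurod6 (-3.42 against 2.32) and the neurotrophin gene Bdnf (-7.44 against -1.89) were low too. Of 13 hippocampal glutamatergic genes 11 lay below every other P30 array, among them Lhx2 (1.20, others 1.54 to 2.46) and Emx2 (0.75, others 1.25 to 2.38), which stood less far apart, while Kcnv1 (0.86 against 0.94) and Zbtb20 (0.16 against 0.17) lay within the range of the others.

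The 26 striatal genes had a median of 1.91 on this array, against -2.74 to -1.89 on the other 11 P30 arrays, and 26 of 26 lay above every one of them, so tissue of the striatum had the values it needs. The 2 lists were composed after the most extreme genes of this array had been seen, and 3 striatal and 2 glutamatergic genes are also in other lists. The 13 glutamatergic genes had a median of -3.18, which is 5.91% of the lowest other P30 array on a linear scale. That is lower than striatal tissue as the smaller part of a hippocampal sample would give. As the list was composed after this array's extreme genes were seen, such a mixture is not excluded. Whether the tissue was dissected elsewhere or the array carries the wrong name stays open, and no biological explanation was tested. The array was kept in its group.

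More genes rose than fell at P60. Background signal common to all probes gained less than the risen genes. As these genes were chosen for rising on the same arrays, background is not excluded as the cause. Relative to the 75th percentile and not in log2, negative controls gained 0.0164 (SE 0.0131) from P60 control to P60 HS arrays and receptor probes 0.00216 (SE 0.00115), against 0.0578 (SE 0.00765) for the median of the 113 risen genes, 83 of which were well above background on all 14 arrays. These values replaced an earlier test of the receptor probes in log2, which lay 0.38 higher in HS (exact permutation p = 0.0906) and decides nothing. Quantile normalization left the median log2 fold change of the 113 risen genes at 0.56 (SE 0.116), from 0.79 in the planned scaling. As these genes were chosen under the planned scaling, this cannot exclude scaling as the cause. The call ended with quantile normalization, where the smallest adjusted p of limma became 0.0533. With normexp background correction the median was 0.27 (SE 0.068) with 10 genes called.

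On the 1 slide that held P60 arrays of both groups, genes chosen without that slide differed by a median of 0.26 (SE 0.14) in the HS direction, against 0.93 elsewhere, and 94 of 113 were higher. The criterion first set for this test, a value within 2 SE of 0, was met and would have pointed to the slide. It was replaced after that value was seen by a comparison with 90 held-out sets of arrays of the same size (median 0.49, range -0.18 to 1.04, 19 of them at or below 0.26), which does not separate slide from HS. The effect of HS itself, which the design names, stays open beside slide. With slide as a random block the median fold change of the risen genes was 0.81 (SE 0.174) and no gene passed, and with slide as a fixed block it was 0.69 (SE 0.248).

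Most genes changed from P60 to P120 in controls, and nonspecific signal on the P120 arrays had the values it needs: the lowest P120 array had a receptor-probe median of -2.18, above the highest of the 40 other arrays (-5.54). Of the P120 arrays 0 shared a scan with another age, so scan batch cannot be told apart from age. Age, which the design names, stays open for any single gene, Pkd2l1, Dbx1 and P2rx5 among them.

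Other splits of the same arrays moved single arrays freely across slides, although most slides held 1 group. They do not bear on slide, scan or background, and tell only whether chance, as random grouping, can be excluded. For genes changed by HS it was excluded at P60 (1 of 100 splits as large, the real one included, 116 genes, highest other 3). At P12 3 of 100 splits were as large as the real count of 2 genes, but another split called 134. Chance was therefore not clearly excluded at P12, and the arrays held a structure whose source was not tested. At P30 (highest other 5) and P120 (highest other 0) the real count was 0 genes. Every split is as large as 0, so the 100 of 100 there could not test chance. For genes whose HS effect differed between ages random grouping was excluded (1 of 100, 2460, highest other 101). The count was 168 with slide as a random block and 1 without the P120 arrays, so slide and dim signal were not excluded. For the HS lists chance was not excluded at P12 (39 of 100, 6 lists, highest other 11), P30 (75 of 100, 6, 13), P60 (95 of 100, 3, 12) or P120 (55 of 100, 5, 14). For genes changed with age it was excluded at each step (1 of 100 each: 9415 against 3591 for P12 to P30, 5156 against 1380 for P30 to P60, 21564 against 20210 for P60 to P120). For lists shifted with age it was not (40 of 100, 9 lists, highest other 14; 74 of 100, 9, 16; 20 of 100, 15, 18).

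In 35 of 334 groups of values 1 array stood apart from the rest of its group by Dixon's test, where chance picks about 1 in 20 groups, or 16.7. P12 control 7 held 8 of them: Ccnb1 at -1.26 (other P12 controls -2.96 to -2.22), Npy 6.04 (4.02 to 4.86), Rgs5 1.72 (-0.32 to 0.21), Rpl28 7.31 (4.98 to 5.83), Dpysl3 -1.21 (0.26 to 1.30), Fbp2 1.11 (-0.48 to 0.09), the ribosomal list 7.96 (5.66 to 6.08) and its median correlation with its group 0.925 (0.965 to 0.976).

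P30 control 3 held 9: Stx1a 2.47 (3.74 to 4.11), Hcn4 -3.45 (-4.05 to -3.83), Ccna2 -1.79 (-4.33 to -3.66), Cdk1 0.23 (-3.01 to -2.03), Col26a1 -4.44 (-2.61 to -2.13), Fbp2 -4.61 (-3.11 to -2.62), Scn4b 5.59 (-1.33 to 0.20), the cell cycle list -1.87 (-4.16 to -3.54) and the CA1 list -1.36 (0.86 to 1.62). P30 control 4 was high in ribosomal genes: Rps18 6.69 (5.07 to 5.63), Rps2 6.75 (5.29 to 5.58) and the list at 6.52 (5.32 to 5.72). P30 control 1 stood apart in Cldnd2 -6.30 (-2.73 to -2.07), Or12d2b -5.27 (-1.87 to -1.70) and Or9m1b -3.01 (-6.04 to -5.24).

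The others were single: Fut7 on P12 control 1 at -6.85 (-6.10 to -5.54), Scn2b on P12 control 3 at -6.69 (-5.31 to -4.37), Dse and Stx1a on P30 HS 4 at -4.92 (-4.59 to -4.52) and 4.81 (4.02 to 4.31), the synaptic vesicle list on P30 HS 6 at 1.68 (2.08 to 2.24), and the receptor probes on P30 HS 3 at -5.54 (-7.47 to -6.82). At P60 they were Cep19 on control 2 at 1.36 (1.79 to 2.02), and Or4c127 and Lsm14b on control 1 at -4.69 (-5.78 to -5.40) and -3.34 (-2.74 to -2.38). At P120 they were Myo18a on HS 2 at 0.23 (-0.09 to 0.04), Trem2 on HS 7 at 1.37 (1.01 to 1.17), and the correlation of control 6 with its group at 0.966 (0.976 to 0.981).

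Of the genes named for HS within an age, the HS effect of 18 differed between the ages in the F test that gave 2460 genes. These were Slc28a1 (adjusted p = 0.0153), Snx30 (0.0186), Or2av10 (0.00711), Trib3 (0.0242), Igfbpl1 (0.0234) and Marcksl1 (0.024), named at P12, Itpripl1 (0.0262), Odam (0.0206), Or52z1 (0.0182) and Dse (0.0326), named at P30, Glp1r (0.0284), Or51i2 (0.0152), Otop1 (0.0343), Or4c127 (0.0274), Aqp2 (0.0385), Or6ae1 (0.0323) and Tasl (0.0132), named at P60, and Krt14 (0.0234), named at P120. P2rx5 (0.0207), Or12d2b (0.0473) and Krt33b (0.0495), named for age in controls, passed it too, as did the 10 genes chosen by its p. Without the P120 arrays 1 of 20496 genes passed this test.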

How the results depend on the processing

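The alternatives that leave out arrays, and the second scaling of the lists, were chosen only after the results had been seen; the others were fixed before the data were examined. Of 215 alternatives for results that answer a comparison, 118 gave the same result and 97 moved it, and of 1432 for named genes 1242 gave the same result, 144 a weaker one, 36 a stronger one and 10 the opposite sign. The cause was not tested for any of them.

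Genes changed by HS at P12 numbered 2 and became 0 with normexp background correction and quantile normalization, with probes well above background on every array, with the series matrix values, with slide as a random or fixed block, on slides that hold both groups, and with a replicate block. They became 71 with array weights, 1203 with all 8 groups in one fit and 2754 with no filter on dim probes, and 0 to 18 with 1 array left out. At P30 the 0 became 5 with all 8 groups in one fit. At P60 the 116 became 0 with quantile normalization, all 8 groups in one fit or slide as a random block, 10 with normexp, 15 with the series matrix values, 210 with slide as a fixed block, 1 on the shared slide, 4 with a replicate block, 399 with array weights, and 0 to 199 with 1 array left out. At P120 the 0 became 221 with no filter on dim probes, 13 with probes well above background on every array, 4 with the series matrix values, 4 with a replicate block, 402 with array weights, and 0 to 530 with 1 array left out.

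The 2460 genes whose HS effect differed between ages became 544 with quantile normalization, 145 with normexp, 1 with probes well above background on every array, 79 with the series matrix values, 168 with slide as a random block, 1583 without P12 control 7, 2268 without P30 control 3, 1 without the P120 arrays, and 0 without these, P12 control 7 and P30 control 3. Genes changed with age from P12 to P30 (9415) became 4844 with normexp, 4363 with probes well above background on every array, 3282 with the series matrix values, 6260 with slide as a random block and 6146 without the P120 arrays. From P30 to P60 the 5156 became 2483 with quantile normalization, 2544 with normexp, 1857 with probes well above background on every array, 1838 with the series matrix values, 2428 with slide as a random block and 2256 without the P120 arrays. From P60 to P120 the 21564 became 9215 with probes well above background on every array and 6326 with the series matrix values.

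With an estimated correlation between genes the HS lists became 0 at P12, 0 at P30, 0 at P60 and 0 at P120, and the age lists 1, 1 and 0. With quantile normalization they became 2 at P12, 3 at P30 and 0 at P120, and 2 from P60 to P120, and with normexp 2, 3, 0 and 1. The 3 lists of P60 became 6 with slide as a fixed block and 6 with a replicate block, and the 9 of P30 to P60 became 5 without the P120 arrays. Co-expression modules became 2 at P60 and 1 at P120 with fewer genes clustered, and 1 at P12 and 1 at P120 with quantile normalization.

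Named genes turned to the opposite sign in these cases. Cox4i1 at P12 became 0.04 with quantile normalization and 0.06 with normexp. With slide as a fixed block, and on slides holding both groups, Cplx2 at P30 became 0.18 and 0.18, and Gfap at P60 0.39 and 0.39. From P60 to P120, Trib3 became -0.03 and Itgam -0.10 with quantile normalization, and Gabrg3 -0.67 with it and -0.16 with normexp.

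The labels state no pairing of the 2 groups by replicate number, so the replicate block was kept as an alternative only. After removal of group means, correlations between same-numbered arrays ran from -0.26 to 0.34 at P12, -0.20 to 0.13 at P30, -0.10 to 0.25 at P60 and -0.24 to 0.48 at P120. They were not compared with those of other pairs, so they do not settle whether animals were paired.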

Other observations

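The lists, modules and genes of this part were planned, while the fits without P12 control 7 or P30 control 3, the random lists of matched level and the place of P30 control 1 between the ages were chosen only after the results had been seen.

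Many of the systems that acute seizures are known to engage had no list call for HS at any age with all arrays in the fit. Immediate-early genes had medians of 0.01 at P12, 0.18 at P30, -0.01 at P60 and 0.01 at P120, and were called upward at P30 without P30 control 3 (adjusted p = 0.034, median 0.21). In the same order of ages, heat-shock chaperones had 0.07, 0.10, -0.06 and 0.01, and inflammatory mediators -0.10, -0.02, 0.06 and -0.05. The unfolded protein response had -0.02, 0.03, 0.05 and -0.05, and glucocorticoid-responsive genes 0.05, -0.16, 0.14 and 0.01. Among genes of transmission and excitability, GABA signalling had 0.07, -0.01, -0.08 and 0.01, glutamate receptors 0.06, 0.07, -0.04 and 0.01, and voltage-gated and HCN channels 0.24 (adjusted p = 0.0507), 0.03, -0.07 and -0.02. Circadian clock genes had 0.00, -0.03, 0.03 and 0.01. A list without a call is not thereby shown to be unchanged.

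Cell-type lists without a call had medians of either sign. Myelin genes had medians of 0.37, -0.15, 0.27 and 0.07, choroid plexus genes 0.31, 0.21, 0.44 and -0.06, and dentate granule cell genes -0.12, 0.33, 0.18 and -0.06. CA3 pyramidal cell genes had 0.19, -0.04, -0.22 and -0.09, with 0 of 9 higher in HS animals at P120. Thalamic genes had 0.28, 0.05, -0.07 and -0.04, interneurons and neuropeptides -0.14, 0.16, -0.04 and 0.04, and astrocytes 0.04, 0.06, -0.01 and -0.07. At P30 several of these rested on P30 control 3: without it the medians were -0.05 for dentate granule cells, 0.06 for myelin, -0.25 for CA3 and 0.03 for interneurons.

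Clustered over HS and control arrays of an age together, genes of several lists fell into the same module. At P60 module 3 held 9 of the 10 clustered myelin genes, where 1.12 are expected (Fisher's exact adjusted p = 3.81e-06), module 2 held 6 of 6 red blood cell genes (0.000339), and module 11 held 7 of 9 immediate-early genes and 6 of 6 CA1 pyramidal cell genes (2e-06 for both). At P120 module 5 held 16 of 16 ribosomal genes (2.49e-17) and 5 of 8 of oxidative phosphorylation (0.00326), and module 2 held 6 of 6 CA1 genes (0.000856). At P30 meningeal genes shared a module (4 of 5, 0.000223), and at P12 myelin genes (8 of 14, 0.000128). None of these modules passed the exact permutation test between HS and control after adjustment (smallest adjusted p 0.112 at P12, 0.273 at P30 and 0.112 at P120; module 1 alone passed at P60).

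Random lists of the same level show what brightness alone gave at P12. The ribosomal median of -0.46 lay below the range that holds 95% of them (-0.38 to -0.20), but it was -0.19 without P12 control 7 and -0.07 after quantile normalization. Of the other 28 lists 8 lay outside the range of their own random lists as well. Downward these were cell cycle (-0.19, random lists -0.08 to 0.25), endothelium (-0.22, -0.14 to 0.21), microglia (-0.22, -0.18 to 0.19), oxidative phosphorylation (-0.33, -0.32 to -0.12) and red blood cells (-0.39, -0.37 to 0.20), with medians of -0.22, -0.24, -0.20, -0.12 and -0.21 without P12 control 7. Upward they were channels (0.24, -0.11 to 0.17), the synaptic vesicle cycle (0.17, -0.23 to 0.13) and myelin genes (0.37, -0.16 to 0.20), with 0.12, -0.02 and 0.34 without it.

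Red blood cell genes and the other genes that fell from P30 to P60 behaved differently on P30 control 1, the 1 control of P30 that was scanned with P60. For the genes that fell it lay 0.34 of the way from P60 to P30, as a scan batch requires, and P30 HS 6, in a scan apart from both, lay at 0.32. For red blood cell genes it lay at 0.88 and P30 HS 6 at 1.16, inside the range of the other controls (0.82 to 1.39), so the fall of Slc4a1, Hbe2 and the other red cell genes was also seen within the shared scan. With 1 array this rests on 1 animal.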
